A study of Mus musculus with 24 samples.

How the data were processed

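The values analysed were the submitters' log2 signals of 45101 Mouse430_2 probe sets in 24 arrays, which their processing notes describe as made by RMA with the affy package; RMA corrects background, quantile normalizes the arrays and summarises the probes of each probe set. The package versions and a genome build are not given in the sources used here. The value tables held no missing values, and 0 of their value columns belonged to no sample. The 64 control probe sets were left out of the gene tests. A single gene symbol was listed for 34945 probe sets, several symbols for 932 and none for 9160. Each gene was represented by the probe set with the highest mean log2 signal over the 24 arrays among those with a single symbol, which gave 18193 genes. Of these, 18032 matched an Entrez identifier in a mouse gene table of assembly GRCm38.p6, which was used for symbols, chromosomes and the order of genes only, so no coordinates are printed.

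Genes were tested with limma 3.58.1 in R 4.3.3, in a linear model with a mean for each of the 8 groups of 3 arrays, 16 residual degrees of freedom and empirical Bayes moderated variances. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. The model gave 17 contrasts. Of these, 11 are the responses to anti-CD3 within each genotype and averaged over genotypes and the knockouts against wild type in each state. The other 6 are differences between responses, the last of these the departure from additive effects of the knockouts. P values were two-sided and adjusted within each contrast by the Benjamini-Hochberg method, and a gene is said to have risen, fallen or been called when its adjusted p was under 0.05. Errors of log2 changes are standard errors from limma, and SD is used where stated. The mouse numbers in the labels were taken to pair the untreated and stimulated arrays of an animal, although ElkKO arrays correlated better across numbers 1 and 2 than within them. Changes within mice use the labelled pairs, and are also given with these numbers exchanged. The model left this pairing out, and a fit with mouse as a block, which has 8 residual degrees of freedom for the responses, is given beside each result whose call it changed. In a check over 8361 genes, the 12 pairs correlated at −0.035 to 0.85 after the group means were removed, 10 of them above 0.1, and 9 untreated arrays correlated best with the stimulated array of their own number.

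Genes named in the text followed a rule set before the data were examined. Per contrast these are called genes that changed the same way in each mouse (responses) or whose groups did not overlap (genotype comparisons), a separation that chance alone gives for 10% of genes with 3 against 3. The rule took up to the 10 largest rises and falls in the wild-type response and in the combined-knockout response difference, up to 5 each way elsewhere, and up to 4 members of each gene list with the smallest adjusted p. Elk1, Elk3, Elk4 and Srf were always included, and clone-like symbols were counted but not named. Genes named outside the rule are said to be chosen after their values were seen.

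Fixed before the data were examined were also 24 gene lists. The signalling lists were immediate early genes controlled by ternary complex factors and Srf (TCF-SRF), cytoskeletal genes controlled by Srf with myocardin-related factors (MRTF-SRF), the Egr, Nab and Id3 axis, the AP-1 family, Nr4a and negative selection genes, NF-kB targets, ERK feedback regulators, NFAT and calcium targets, and T cell receptor signalling components. The cell type lists were DP thymocyte genes, positive selection and maturation genes, and markers of mature single-positive and innate T cells, of double-negative thymocytes, of B cells, of macrophages and dendritic cells, of granulocytes, of erythroid cells and of epithelium and stroma. The others were cell cycle genes, heat shock and stress genes, interferon response genes, the ternary complex factor and Srf family, p53 and apoptosis genes, and 4 sex-linked genes. The lists were written from general knowledge and not from these arrays, and some genes are in more than 1 list. Each was tested against all other genes with camera at its preset correlation of 0.01 and again with a correlation estimated from the residuals, adjusted over the 24 lists. Counts of members adjusted over the list alone are given beside the counts over all genes.

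The labels give no labelling dates, so a labelling batch was only inferred from the separate levels of the dap spike-in. Scores per mouse (the median log2 change over a gene set) were compared by exact two-sided permutation tests between genotypes and by an F statistic with 100000 permutations over the 4 genotypes. With 3 mice against 3 an exact p cannot be under 0.1. In data simulated on the same design, with 18193 genes, the wild-type response recovered 87% of genes changed 2-fold and 99% of those changed 4-fold. For untreated SapKO against wild type these shares were 79% and 100%, and for the response difference of ElkSapKO against wild type 47% and 92%. False calls were 8 of 194, 11 of 190 and 7 of 146 in these comparisons. In the simulated wild-type response camera called the raised list and 0 of 50 unchanged lists. The simulated noise was independent between genes and arrays, so this does not check for false list calls among correlated genes. Each gene also had 1 spread in all simulated arrays, whereas limma weights of the real arrays ran from 0.069 to 3.39, both in untreated ElkSapKO. The recovered shares and false calls may thus not hold for contrasts with ElkSapKO. Quantile normalization applied again and median centring moved the median change of all genes by less than 0.1 log2 in each of the 17 contrasts. The numbers of genes called higher and lower moved more, as given below for ElkKO and ElkSapKO.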

Results

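Messenger RNA was measured on Affymetrix Mouse430_2 arrays in CD4 and CD8 double-positive (DP) thymocytes, the immature T cells in the thymus that are selected on the strength of their T cell receptor signal. The 24 arrays came from 12 male mice aged 8 weeks, 3 each of wild type (WT), SapKO, ElkKO and the combined knockout ElkSapKO. Sap and Elk were read here as Elk4 (SAP-1) and Elk1, which are ternary complex factors: ETS-family proteins that bind DNA together with serum response factor (Srf) and are activated by ERK kinases. From each mouse, sorted and rested DP cells were kept for 30 min on plates coated with anti-CD3, which engages the T cell receptor complex, or on uncoated plates. This gave 8 groups of 3 arrays, and the number of arrays limits the precision of each value. The series asks what ternary complex factors do in positive selection. No pair of arrays correlated above 0.9968, and the first and second principal components held 31.2% and 19.8% of the variance.

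Some measures of array quality moved with genotype. The 3′ minus 5′ signal of Actb, which grows as RNA degrades, was 0.224 ± 0.074 log2 (SD, 6 arrays) in WT, 0.196 ± 0.025 in SapKO, 0.495 ± 0.11 in ElkKO and 0.714 ± 0.19 in ElkSapKO. The dap spike-in, a bacterial RNA that is added before labelling, was at 6.41 to 7.22 log2 in both arrays of WT mice 1 and 2 and SapKO mice 1 and 3. In the other arrays it was at 9.33 to 10.3, which included all 12 of ElkKO and ElkSapKO. The untreated array of ElkSapKO mouse 2 stood apart, with an interquartile range of relative log expression of 0.826 against 0.179 to 0.363 in the other 23 arrays.

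**Figure D1:**
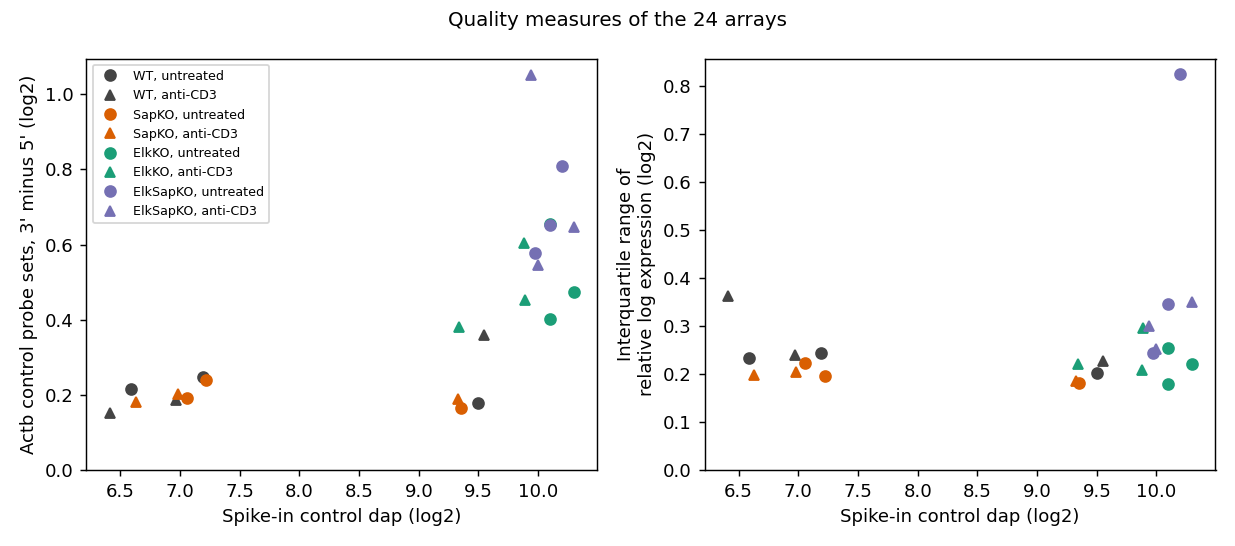
Quality of the 24 arrays, a point per array coloured by genotype: the log2 signal of the dap spike-in on the x axes, against the 3′ minus 5′ log2 signal of Actb (left) and the interquartile range of relative log expression (right). The ElkSapKO arrays lie at 0.545 to 1.05 for Actb against 0.151 to 0.359 in WT, and the untreated array of ElkSapKO mouse 2 lies alone at 0.826 on the right.

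The knockouts were checked first. Elk4 signal in untreated cells was 10.47 ± 0.185 log2 in WT (SD, n = 3), 7.053 ± 0.2 in SapKO and 7.057 ± 0.868 in ElkSapKO, with 10.69 ± 0.168 in ElkKO. Elk4 was thus 10.7-fold lower in untreated SapKO (log2 −3.42 ± 0.268, adjusted p = 8.32e-08) and lower by log2 −3.42 in untreated ElkSapKO (adjusted p = 1.13e-07, but 0.175 with only those 6 arrays in the fit). In stimulated cells it was 8.46-fold lower in SapKO (adjusted p = 4.72e-07) and 7.94-fold lower in ElkSapKO (adjusted p = 1.03e-06). The 3 other Elk4 probe sets differed from WT by −0.84, 0.02 and −1.21 in untreated SapKO, and where the deletion lies relative to each is not known here. Elk1 signal was near background in each genotype, at 4.941 ± 0.266 in untreated WT and 4.394 ± 0.336 in ElkKO (log2 −0.55, adjusted p = 0.293), so this probe set does not check the Elk label. The second Elk1 probe set, chosen after its values were seen, was lower in ElkKO, at 3.676 to 3.878 untreated and 3.823 to 4.117 stimulated. In WT it was at 4.254 to 4.622 and 4.22 to 4.551, and in untreated ElkSapKO at 3.691 to 4.523. These signals are near background too, so this check is weak. The third differed by 0.03 in untreated ElkKO. Elk3, the remaining ternary complex factor, differed by −0.999 in untreated ElkSapKO (adjusted p = 0.0678, and 0.00158 without the untreated array of ElkSapKO mouse 3).

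In WT cells 30 min of anti-CD3 raised genes that encode immediate early transcription factors and feedback proteins. The question here is which genes T cell receptor engagement switches on in DP cells. Egr2 rose at least 153-fold (log2 7.26 ± 0.322, adjusted p = 2.15e-12) and Egr1 111-fold (6.80 ± 0.266, adjusted p = 3.21e-13), both zinc finger factors needed for T cell development. Cd69, an early activation marker that retains cells in the thymus, rose at least 58.1-fold (adjusted p = 7.89e-07), and Nr4a1, an orphan receptor induced in proportion to receptor signal, 37-fold (adjusted p = 2.02e-07). Fos rose 22.4-fold and Fosb at least 8.05-fold, both partners of Jun in AP-1, and Junb rose 5.67-fold. A fold is given as at least where the lower group mean was within the range of Xist, which is not expressed in male cells and was at most 5.07 log2; untreated WT cells had Egr2 at 4.453, Cd69 at 4.953 and Fosb at 4.011. The inhibitor-like NF-kB proteins Nfkbid and Nfkbiz rose 15.8-fold and 13.8-fold, the early response gene Ier2 12.8-fold, and the MAP kinase phosphatases Dusp2 and Dusp5 8.64-fold and 6.64-fold. Rag1, which rearranges receptor genes, fell by log2 0.71 (1.63-fold lower, adjusted p = 0.00078). In total 60 genes rose and 4 fell. The 3 further genes that fell were Socs3, a cytokine signal inhibitor (2.42-fold lower, adjusted p = 0.021), the chemokine receptor Ccr7 (2.33-fold lower, adjusted p = 0.0173) and Txnip, a regulator of glucose uptake (2.22-fold lower, adjusted p = 0.00591). The call of Socs3 was lost without any one of the 6 arrays (adjusted p 0.0565 to 0.187) and with median centring (0.064). That of Ccr7 was lost without the untreated array of WT mouse 1 (adjusted p = 0.184) or 2 (0.0767), the stimulated array of mouse 2 (0.123) or 3 (0.0812), and with mouse as a block (0.099). That of Txnip was lost without the untreated array of mouse 2 (0.075) and with only the WT arrays in the fit (0.0825). Leaving out the untreated or stimulated array of mouse 2 left 41 or 35 genes, while 100 were called without the untreated array of ElkSapKO mouse 2 and 142 with array weights.

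Of the 24 TCF-SRF immediate early genes, 11 rose and none fell in WT (camera adjusted p = 2.05e-44; 2.56e-05 with an estimated correlation); adjusted over the list alone, 14 rose and Arc fell. The Egr, Nab and Id3 axis had 4 of 12 members up (5 adjusted over the list alone; camera adjusted p = 1.44e-13), and the AP-1 family 4 of 14 (5 over the list alone; 1.22e-14). The Nr4a and negative selection list had 5 of 15 up (7 over the list alone; 5.21e-16), among them Nr4a2 at 4.91-fold. ERK feedback regulators rose in 2 of 20 genes, Dusp2 and Dusp5 (4 over the list alone; camera adjusted p = 2.27e-08), and NFAT and calcium targets in 2 of 18, Egr2 and Egr3 (4 over the list alone; 0.000206). These 5 lists kept their calls with an estimated correlation, with adjusted p of 0.00546 or less. NF-kB targets were called as raised with 2 of 21 genes up (5 up and 1 down over the list alone; camera adjusted p = 0.000478, adjusted p = 0.0859 with an estimated correlation), although their median change was −0.02. Egr3 itself rose 2.07-fold (adjusted p = 0.0111), a call lost without the untreated array of WT mouse 1 (0.0827) or 3 (0.0549) or the stimulated array of mouse 2 (0.137), and with only the WT arrays in the fit (0.113). These values are from its brightest probe set; the other, chosen after its values were seen, rose by at least log2 7.33 (adjusted p = 1.4e-13 among all probe sets; untreated 3.096). Srf rose 2.01-fold (adjusted p = 0.0104), a call lost without the untreated array of mouse 2 (0.114), the stimulated array of mouse 2 (0.0527) or 3 (0.0844), and with mouse as a block (0.0572).

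Lists of T cell identity and of other cell types were tested in the same way in the WT response. Positive selection and maturation genes had 4 of 28 members up and 2 down (9 and 4 adjusted over the list alone; camera adjusted p = 0.317), and receptor signalling components had 1 of 26 up, the inhibitory receptor Cd5 (2 over the list alone; 0.265). DP thymocyte genes were called as lowered with 1 of 22 down, Rag1, and 1 up (the same numbers over the list alone; camera adjusted p = 0.0449, adjusted p = 0.381 with an estimated correlation). Mature and innate T cell markers were called as lowered with 0 of 18 genes past the threshold (1 over the list alone, S1pr1; 0.0286, adjusted p = 0.423 with an estimated correlation). So were cell cycle genes with 0 of 29 (0 over the list alone; 0.0449, adjusted p = 0.696 with an estimated correlation). No member passed among 22 MRTF-SRF cytoskeletal genes (camera adjusted p = 0.102). The same held for 13 double-negative thymocyte, 12 B cell, 20 macrophage and dendritic cell, 11 granulocyte, 7 erythroid and 20 epithelial and stromal markers, and 21 interferon response genes (camera adjusted p from 0.068 to 0.909; 0 over each list alone). The 18 p53 and apoptosis genes had 0 past the threshold (3 up over the list alone; 0.0992). The 20 heat shock and stress genes had 1 up and 1 down (2 and 1 over the list alone; 0.798). The 18 family members of ternary complex factors and Srf had 1 up, Srf (1 over the list alone; 0.943), and the 4 sex-linked genes 0 (0 over the list alone; 0.798).

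Cells without Sap, Elk or both were also stimulated, to ask which of these genes still respond. SapKO cells raised 62 genes and lowered 4: Egr1 rose 68.2-fold, Egr2 38.1-fold (untreated 5.072, at the edge of the range of Xist), Cd69 by log2 5.14, Nr4a1 by 5.11 and Fos 16.1-fold, while Socs3 fell by 1.49 (adjusted p = 0.00383). ElkKO cells raised 36 genes and lowered Rag1 alone (log2 −0.62, adjusted p = 0.00643): Egr2 rose at least 122-fold, Egr1 96.5-fold, Nr4a1 by log2 5.31 and Cd69 by 5.20. ElkSapKO cells raised 60 genes and lowered 3, with Egr1 up 74.7-fold, Egr2 at least 36.7-fold, Cd69 by at least log2 6.16 and Nr4a1 by 4.98; the genes that fell were Txnip (log2 −1.05, adjusted p = 0.0157), the muscle gene Smyd1 (−0.63) and Rag1 (−0.62). The fall of Rag1 in ElkKO was not called without the untreated array of mouse 3 (adjusted p = 0.0566) or the stimulated array of mouse 2 (0.0781), or with only the ElkKO arrays in the fit (0.112). In ElkSapKO the fall of Txnip was not called without the stimulated array of mouse 1 (0.0622), 2 (0.0865) or 3 (0.0665). That of Smyd1 was lost without the untreated array of mouse 1 (0.0795) or 2 (0.127) or the stimulated array of mouse 1 (0.0842), 2 (0.392) or 3 (0.0934), and with mouse as a block (0.114). With only the ElkSapKO arrays in the fit none of its 3 falls was called (adjusted p 0.267 to 0.999), and with median centring Rag1 was not (0.0559). Srf changed by log2 0.93 in SapKO (adjusted p = 0.0234), 0.81 in ElkKO (0.124, and 0.0256 without the untreated array of ElkSapKO mouse 2) and 0.95 in ElkSapKO (0.0203). The Srf calls in SapKO and ElkSapKO were lost with mouse as a block (0.0901 and 0.0812) and with probe sets averaged (0.144 and 0.426). In SapKO the call was also lost without any one of the 6 arrays (0.0839 to 0.133), and in ElkSapKO without the untreated array of mouse 1 (0.0609) or the stimulated array of mouse 2 (0.0632) or 3 (0.134). SapKO counts were 100 without the untreated array of ElkSapKO mouse 2, 229 with array weights and 157 with only its own arrays in the fit. ElkKO counts fell to 22, 21 and 24 without the untreated array of mouse 2 or 3 or the stimulated array of mouse 2, and were 186 with array weights. ElkSapKO counts were 696 with array weights, 114 and 216 without the untreated array of mouse 1 or 3, 36 without the stimulated array of mouse 2, and 15 with only its own arrays in the fit.

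The TCF-SRF immediate early list rose in each knockout. The members up were 10 of 24 in SapKO (12 up and 1 down adjusted over the list alone; camera adjusted p = 1.94e-54), 9 in ElkKO (12 and 1; 6.46e-44) and 10 in ElkSapKO (11 and 1; 3e-21). Each was also called with an estimated correlation (adjusted p of 0.00197 or less). The Egr, Nab and Id3 axis rose in 3 of 12 genes in SapKO (4 over the list alone; camera adjusted p = 1.17e-11), and 2 in ElkKO (4 over the list alone; 1.48e-08). In ElkSapKO it rose in 2 (3 up and 1 down over the list alone; 0.000238, adjusted p = 0.0286 with an estimated correlation). AP-1 genes rose in ElkSapKO with 3 of 14 members, Fos, Junb and Maff (5 over the list alone; 0.000357, adjusted p = 0.129 with an estimated correlation). Positive selection and maturation genes were called as raised in SapKO with 6 of 28 members up, Cd69 and Cd5 among them, and 1 down (9 and 3 over the list alone; 0.000138, adjusted p = 0.0512 with an estimated correlation), although their median change was −0.05. They were called in ElkSapKO too, with 2 up (7 up and 3 down over the list alone; 0.049, adjusted p = 0.312 with an estimated correlation, and 0.155 with mouse as a block). The NFAT list in ElkKO (1 of 18 up, Egr2; 2 over the list alone; camera adjusted p = 0.0207) was not called with an estimated correlation (adjusted p = 0.0635) or with mouse as a block (0.0548). The family of ternary complex factors and Srf was called as raised in ElkSapKO with 1 of 18 up, Srf (2 over the list alone; 0.0444, adjusted p = 0.112 with an estimated correlation, 0.125 with mouse as a block and 0.059 without Elk1 and Elk4). The 4 sex-linked genes were also called there, with 0 past the threshold (1 over the list alone, Xist, with camera adjusted p = 0.00215, and 0.0319 with an estimated correlation). That list was a check of labels, and Xist had a mean of only 4.44 over the arrays. Its call is therefore a reason for caution about the other lists called in the ElkSapKO response.

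Averaged over the 4 genotypes, 185 genes rose and 79 fell. Egr1 rose by log2 6.43, Egr2 by at least 6.16, Cd69 by at least 5.59, Nr4a1 by 5.15 and Fos by 4.11, and the falls were led by Socs3 (−1.25), Txnip (−1.07), the stress gene Ddit4 (−0.80), Slfn1, a quiescence gene (−0.75), and Rag1 (−0.64). Each of these was called without any one of the 24 arrays. The same direction in all 12 mice was required by the naming rule, so it is no further support. TCF-SRF genes had 12 of 24 members up and 1 down (16 and 2 adjusted over the list alone; camera adjusted p = 1.11e-50). NF-kB targets had 5 of 21 up (5 up and 1 down over the list alone; 9.55e-07, adjusted p = 0.0139 with an estimated correlation). Positive selection genes had 9 of 28 up and 3 down (9 and 5 over the list alone; camera adjusted p = 0.0321, adjusted p = 0.327 with an estimated correlation, and 0.369 with mouse as a block), with a median of −0.05. The count was 493 without the untreated array of ElkSapKO mouse 2 and 1091 with array weights.

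Whether loss of the factors changed the size of the response was tested directly. In the averaged response 46 genes rose at least 2-fold, and in each genotype all 46 changes were positive. The median log2 change over these genes in each mouse averaged 1.71 ± 0.33 in WT (SD, n = 3), 1.94 ± 0.15 in SapKO, 1.49 ± 0.26 in ElkKO and 1.72 ± 0.031 in ElkSapKO. These are differences from WT of 0.23, −0.22 and 0.0185 (exact permutation p = 0.4, 0.4 and 0.8; F permutation p = 0.2). Over the 24 TCF-SRF genes this median averaged 0.79 ± 0.13 in WT, 0.469 ± 0.11 in SapKO, 0.505 ± 0.23 in ElkKO and 0.527 ± 0.13 in ElkSapKO. Each knockout differed with an exact permutation p of 0.1, the smallest that 3 mice against 3 allow, and the F permutation p was 0.13. These pairs follow the mouse numbers in the labels, although ElkKO arrays correlated better across numbers 1 and 2 than within them. With ElkKO numbers 1 and 2 exchanged, its score over the induced genes had an SD of 0.18 and differed from WT by −0.213 (exact permutation p = 0.4; F permutation p = 0.16). Its TCF-SRF score was then 0.537 ± 0.052, with an exact permutation p of 0.1, and the F permutation p was 0.027.

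**Figure D2:**
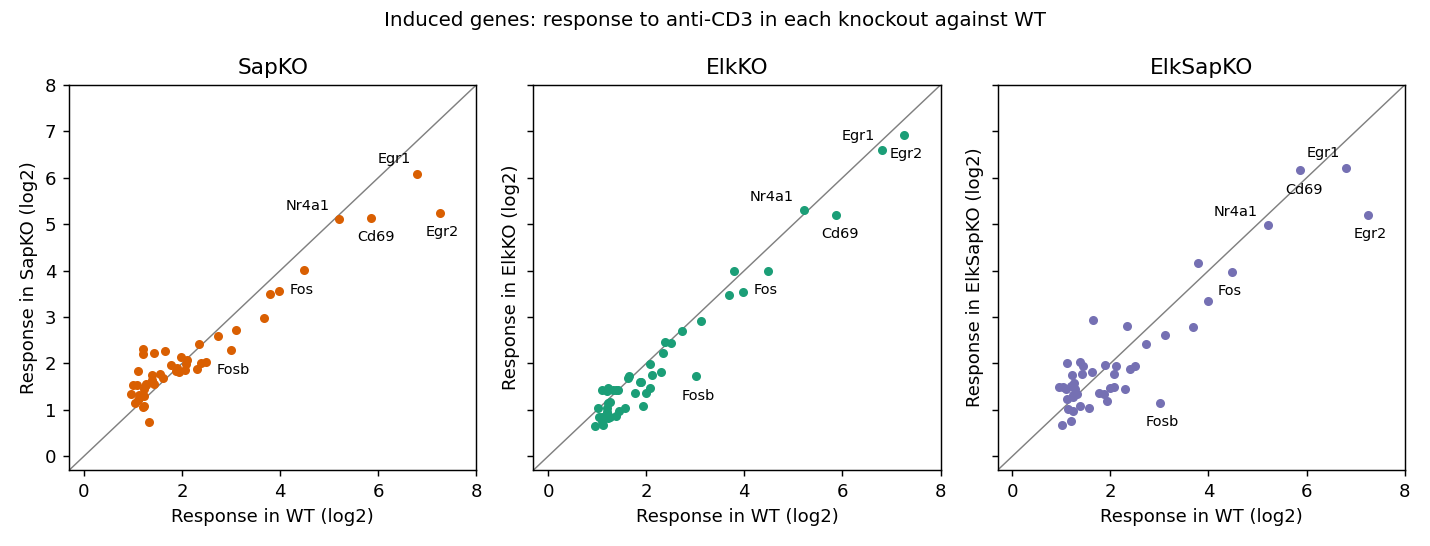
Log2 change on anti-CD3 of the 46 genes that rose at least 2-fold in the averaged response, in each knockout (y axis) against WT (x axis), a point per gene and a line of equal change. Egr2 lies below the line in SapKO (5.25) and ElkSapKO (5.20) and near it in ElkKO (6.93), against 7.26 in WT.

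Gene by gene, limma called 0 genes in each of the 5 differences between responses and in the departure from additive effects. There were 143 genes at an unadjusted p under 0.05 for SapKO against WT, 165 for ElkKO, 982 for ElkSapKO, 361 for ElkSapKO against SapKO, 625 for ElkSapKO against ElkKO and 185 for non-additivity. Adjusted over the TCF-SRF list alone, the rise of Egr2 was smaller in SapKO than in WT, with a difference of log2 −2.003 ± 0.455 (adjusted p = 0.00578; 1 over all genes). In ElkSapKO it was smaller too, with a difference of −2.06 (0.00431; 0.703 over all genes). Egr3 differed by −1.01 in ElkSapKO against WT (0.0129 over the list alone) and Fosb by −1.86 (0.0128 over the list alone), whose untreated signal was also near background, at 4.011 in WT and 3.939 in ElkSapKO. Part of the Egr2 difference lies in untreated signals near background, 4.453 in WT, 5.072 in SapKO and 4.361 in ElkSapKO. In stimulated cells alone it was −1.384 in SapKO against WT (adjusted p = 0.206) and −2.151 in ElkSapKO (0.00109). The second Egr2 probe set, chosen after its values were seen, gave −1.452 (adjusted p = 0.0195 among all probe sets) and −1.551 (0.00209). The change of Egr2 was 7.26 ± 0.61 (SD, n = 3) in WT, 5.25 ± 0.39 in SapKO, 6.93 ± 0.9 in ElkKO and 5.20 ± 0.63 in ElkSapKO. The second probe set of Egr3, chosen after its values were seen, changed by 7.33 ± 0.48 in WT, 4.78 ± 0.16 in SapKO, 7.35 ± 0.19 in ElkKO and 4.81 ± 0.9 in ElkSapKO. Its untreated means, 3.096, 3.336, 3.017 and 2.735, were below the range of Xist (4.07 to 5.07), so these changes are lower bounds. In stimulated cells alone it differed from WT by log2 −2.314 in SapKO (adjusted p = 4.86e-05 among all probe sets) and −2.883 in ElkSapKO (1.75e-06). With every probe set tested, this was the only one called in the response differences of SapKO (log2 −2.55, adjusted p = 0.0195) and ElkSapKO (−2.52, adjusted p = 0.0235) against WT and of ElkSapKO against ElkKO (−2.54, adjusted p = 0.0207). Ncoa7, a nuclear receptor coactivator also chosen after its values were seen, changed by 1.28 ± 0.21 in WT, −0.0557 ± 0.19 in SapKO, 1 ± 0.3 in ElkKO and 0.216 ± 0.64 in ElkSapKO. Its response difference of SapKO against WT was called in 5 alternatives (adjusted p 0.000744 to 0.0395), among them the fit without the untreated array of ElkSapKO mouse 2 (log2 −1.34, adjusted p = 0.0206). Its other probe set changed by −0.38 ± 0.5 in WT and −0.179 ± 0.21 in SapKO. With ElkKO numbers 1 and 2 exchanged, the SD in ElkKO was 0.63 for Egr2, 0.29 for the second Egr3 probe set and 0.1 for Ncoa7, with the means as given.

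**Figure D3:**
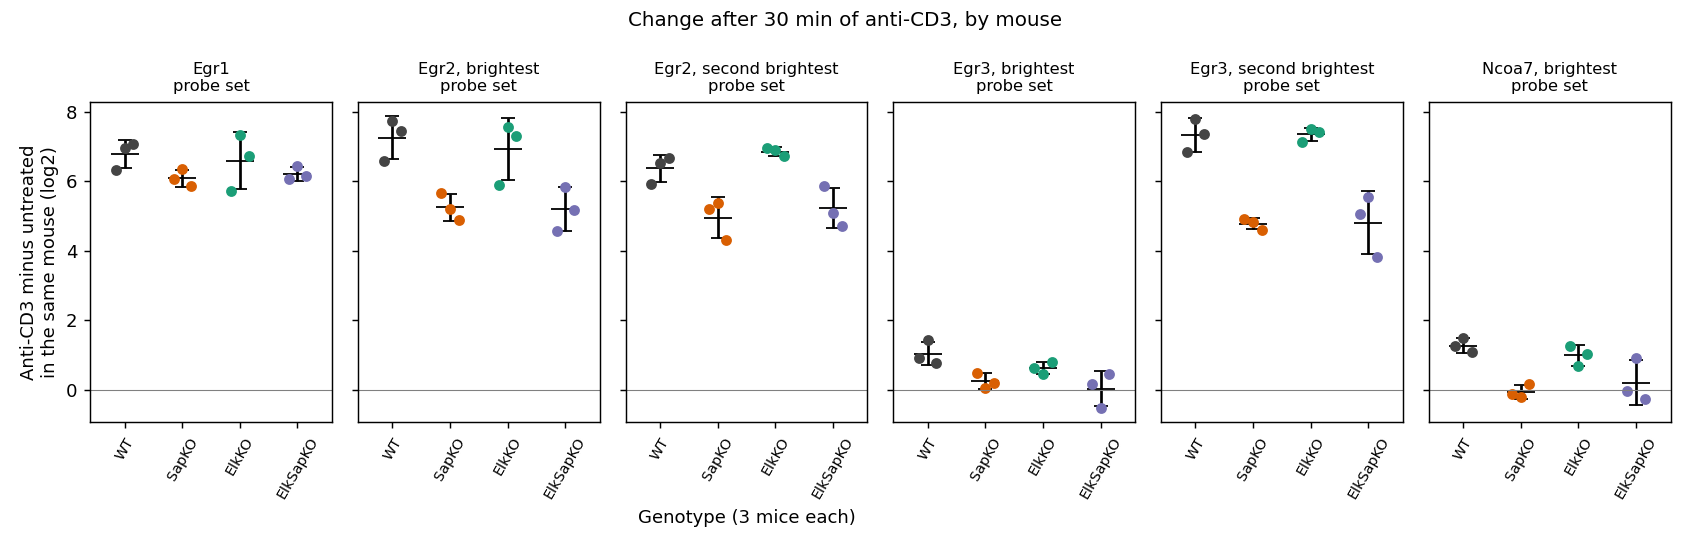
Log2 change on anti-CD3 within each mouse (stimulated minus untreated, paired by the mouse numbers in the labels; points are mice, bars mean ± SD, 3 mice per genotype) for Egr1, for 2 probe sets each of Egr2 and Egr3, and for Ncoa7. On the second Egr3 probe set the mice lacking Sap reach at most 5.54, and the mice having it at least 6.84.

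As lists, TCF-SRF genes had a smaller response than in WT in SapKO (camera adjusted p = 0.0028, adjusted p = 0.575 with an estimated correlation) and ElkSapKO (0.0196, adjusted p = 0.488 with an estimated correlation). The Egr, Nab and Id3 axis had a smaller one in SapKO (0.00136, adjusted p = 0.12 with an estimated correlation), ElkKO (0.0208, adjusted p = 0.508) and ElkSapKO (0.0269, adjusted p = 0.202). Nr4a genes did in ElkKO (0.0208, adjusted p = 0.54 with an estimated correlation), and AP-1 genes in ElkSapKO against WT (0.0311, adjusted p = 0.518) and against SapKO (0.0284, adjusted p = 0.702). Positive selection genes had a larger response in SapKO (0.0253, adjusted p = 0.575 with an estimated correlation). Interferon response genes had a larger one in ElkSapKO (0.0495, adjusted p = 0.202 with an estimated correlation, and 0.0658 with mouse as a block). The 4 sex-linked genes had a larger one in ElkSapKO against WT (0.0275, adjusted p = 0.202 with an estimated correlation) and against SapKO (0.027, adjusted p = 0.218). Each of these list calls was thus lost with an estimated correlation.

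Cells lacking Sap differed from WT before stimulation in few genes, 11 higher and 4 lower. Ctse, an endosomal protease, was 18.6-fold higher in untreated SapKO (log2 4.22 ± 0.195, adjusted p = 5.07e-12). Nmnat1, an enzyme of nuclear NAD synthesis, was 16.3-fold higher (4.03 ± 0.161, adjusted p = 5.03e-13), the retinol-binding protein Rbp7 at least 12.1-fold higher (adjusted p = 7.34e-09; 4.383 in WT), Gcsh of the glycine cleavage system 4.95-fold higher (0.000706) and the relaxin-family hormone Insl5 3.85-fold higher (1.25e-05). Besides Elk4, Ncoa7 was 2.26-fold lower (adjusted p = 0.00567, but 0.0754 without the untreated array of WT mouse 3). Nnt, a mitochondrial transhydrogenase, was 1.92-fold lower (adjusted p = 0.0293, but 0.102 to 0.227 without any one of the 6 arrays). In stimulated SapKO, 11 genes were higher and 2 lower: Ctse 21.4-fold, Nmnat1 15.2-fold, Rbp7 at least 11.1-fold, Gcsh 4.7-fold and Insl5 4.34-fold higher, and Ncoa7 5.72-fold lower (adjusted p = 2.65e-08). Both states, measured in the same mice, shared 11 called genes, each in the same direction. With a gene's probe sets averaged, Ctse was not called in untreated (adjusted p = 0.184) or stimulated SapKO (0.06), nor was Ncoa7 in either state (1 and 0.381). Quantile normalization applied again gave 13 higher and 5 lower in stimulated cells. The untreated count was 8, 8, 9 and 8 without the untreated arrays of WT mouse 2, WT mouse 3, SapKO mouse 1 and SapKO mouse 3, 42 with array weights and 35 with only the groups compared in the fit. The stimulated count was 8 without the stimulated array of SapKO mouse 3, 27 without the untreated array of ElkSapKO mouse 2, and 47 with array weights.

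Interferon response genes were called as higher in untreated SapKO, with 1 of 21 past the threshold, the protease Usp18 (1 over the list alone; camera adjusted p = 1.31e-05, and 0.00547 with an estimated correlation). In stimulated SapKO they were called with 0 (2 over the list alone, Usp18 and Igtp; 3.81e-07, and 0.00152 with an estimated correlation). Usp18 itself was at least 2.58-fold higher in untreated SapKO (adjusted p = 0.0293; 4.712 in WT). That call was lost without the untreated array of WT mouse 2 (0.315) or 3 (0.154) or of SapKO mouse 1 (0.216), 2 (0.126) or 3 (0.187), and with quantile normalization again (0.0707). B cell markers were called as higher with 0 of 12 past the threshold in untreated SapKO (2 over the list alone, Cd79a and Ms4a1; 1.22e-08, adjusted p = 0.0534 with an estimated correlation). This held in stimulated SapKO too (2 over the list alone, Ms4a1 and Spib; 9.9e-08, adjusted p = 0.0519 with an estimated correlation). DP thymocyte genes were called as higher with 0 of 22 past the threshold in untreated (0.0359, adjusted p = 0.568 with an estimated correlation) and stimulated SapKO (0.00034, adjusted p = 0.147). In stimulated SapKO the Egr, Nab and Id3 axis was called as lower with 0 of 12 past the threshold over all genes and 5 over the list alone, Egr1, Egr2, Egr3, Egr4 and Nab2 (camera adjusted p = 5.61e-07, and 0.00587 with an estimated correlation). TCF-SRF genes were called as lower there with 0 of 24 (2 over the list alone, Egr2 and Egr3; 0.000227, adjusted p = 0.206 with an estimated correlation). Macrophage and dendritic cell markers were called as higher with 0 of 20 (0 over the list alone; 0.00458, adjusted p = 0.529 with an estimated correlation).

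**Figure D4:**
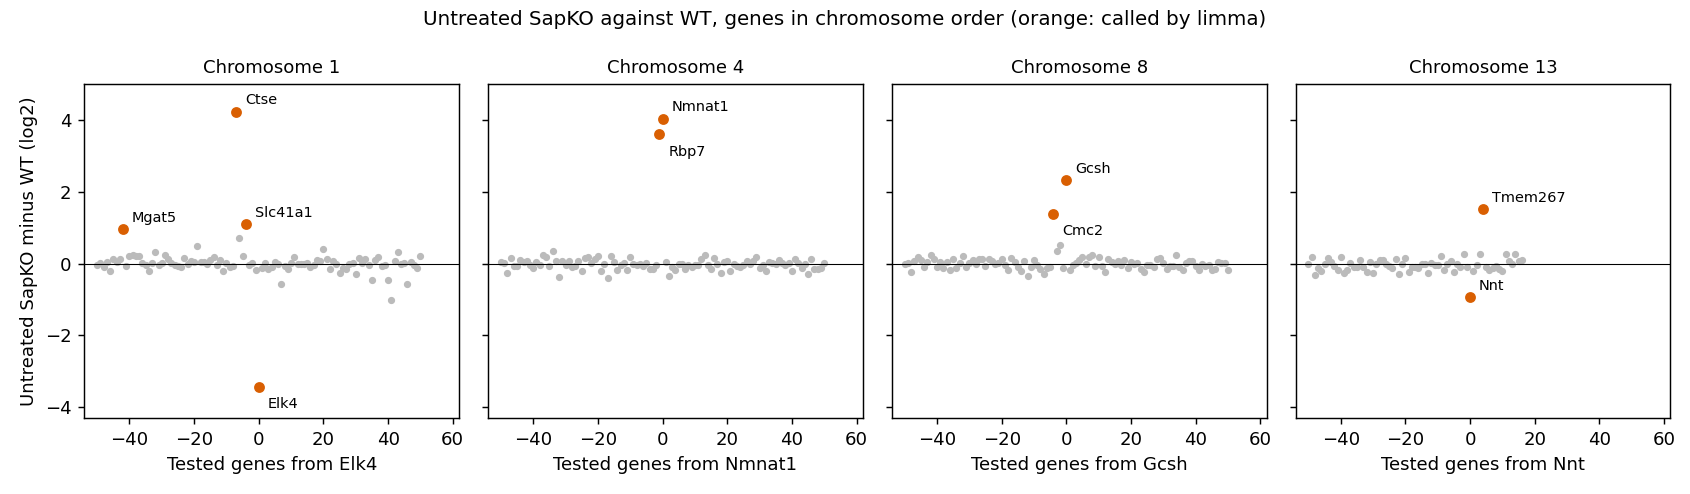
Log2 difference of untreated SapKO minus WT for tested genes in chromosome order, up to 50 genes to each side of Elk4 (chromosome 1), Nmnat1 (4), Gcsh (8) and Nnt (13, with 16 genes after it). Orange points are called genes. Called genes lie within 7 tested genes of each other in each panel: Ctse and Slc41a1 with Elk4, Rbp7 with Nmnat1, Cmc2 with Gcsh, and Tmem267 with Nnt. Mgat5, also called, lies apart at −42 from Elk4.

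Without Elk, 4 genes were higher and 14 lower in untreated cells. Mid1, an X-linked ubiquitin ligase on microtubules, was 6-fold higher (log2 2.59, adjusted p = 0.0018) and Gcsh 4.57-fold higher (adjusted p = 0.00316) than in WT. Lmnb1, which encodes lamin B1 of the nuclear envelope, was 2.18-fold lower (adjusted p = 0.000243) and Ap2b1, a clathrin adaptor subunit, 4.29-fold lower (adjusted p = 0.0147). Cfp, which lies next to Elk1 in the order of tested genes, was at least 2.13-fold lower (adjusted p = 0.0095, at 4.708 in ElkKO). Its untreated call was lost in 4 of 19 alternatives, and stimulated it differed by log2 −1.05 (adjusted p = 0.00911). In stimulated ElkKO, 8 genes were higher and 32 lower: Mid1 4.83-fold higher (adjusted p = 0.00582), Gcsh 4.18-fold higher and Ap2b1 4.98-fold lower (adjusted p = 0.00582). The higher Gcsh rests on the same WT arrays as in SapKO. The 3′ minus 5′ signal of Actb was 0.495 in ElkKO against 0.224 in WT, and all ElkKO arrays had a high spike-in. The Mid1 calls were lost with a gene's probe sets averaged (adjusted p = 0.0808 untreated and 0.08 stimulated). That of Ap2b1 was lost in untreated cells without the array of WT mouse 2 (0.15), ElkKO mouse 1 (0.167) or ElkKO mouse 2 (0.0759), and with the spike-in level as a term (0.0731). Without the stimulated array of ElkKO mouse 2, neither Ap2b1 nor Gcsh was called in stimulated cells (0.0529 each). MRTF-SRF cytoskeletal genes were called as lower with 0 of 22 past the threshold in untreated ElkKO (6 over the list alone, among them the actins Actb and Actg1 and the adhesion protein Zyx; camera adjusted p = 3.9e-05, adjusted p = 0.924 with an estimated correlation). They were also called in stimulated ElkKO (7 over the list alone, Actg1 and Zyx among them; 0.000165, adjusted p = 0.398). Nr4a genes were called as lower in stimulated ElkKO with 0 of 15 past the threshold (3 over the list alone, Nr4a3, Bbc3 and Tnfrsf18; 0.00795, adjusted p = 0.398 with an estimated correlation). AP-1 genes were called as lower with 0 of 14 (3 over the list alone, Fosb, Fosl2 and Maff; 0.0385, adjusted p = 0.493 with an estimated correlation). Quantile normalization applied again gave 7 higher and 11 lower in untreated and 16 and 27 in stimulated cells, and median centring gave 17 and 35 in stimulated cells. Without the untreated array of ElkSapKO mouse 2, which enters through the pooled variance, 106 genes were called untreated and 264 stimulated, and with array weights 964 and 931. With the spike-in level as a term, 5 and 11 genes were called, and within the arrays of high spike-in, where WT had 1 array per state, 0 and 0. The log2 changes kept a median 0.946 and 0.954 of their size with the term and 0.911 and 1.02 within those arrays, with the same sign in all 18 and 40 genes. As the genes were picked on arrays that both fits use again, this is no independent support. With 1 array of that state left out, the untreated count was 5 and 4 without WT mouse 1 and 2, and 3 and 8 without ElkKO mouse 1 and 2. The stimulated count was 13, 11 and 12 without WT mouse 1, 2 and 3, and 9, 3 and 26 without ElkKO mouse 1, 2 and 3.

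Cells lacking both factors differed from WT in many genes: 137 higher and 489 lower untreated, 255 higher and 987 lower stimulated. Untreated ElkSapKO cells had Ctse 16.9-fold higher (adjusted p = 1.98e-11), Nmnat1 5.68-fold higher (3.76e-09) and Rbp7 at least 2.84-fold higher (0.003). Lower were Glipr1 (3.36-fold, adjusted p = 0.000597), Ccr7, which guides mature thymocytes to the medulla (2.62-fold, 0.00457), S1pr1, which guides their exit (2.35-fold, 0.0118), and Runx1, a T cell transcription factor (log2 −1.35, 0.0108). S1pr1 and Runx1 were not called without the untreated array of WT mouse 1 (0.0899 and 0.0741) or with the spike-in level as a term (0.0612 and 0.077). In stimulated cells Ctse was 18.9-fold higher (adjusted p = 9.09e-12). Ncoa7 was 5.67-fold lower (5.86e-08), Egr2 4.44-fold (0.00109), its corepressor Nab2 at least 4.42-fold (0.000786), the endosomal GTPase Rab5c 4.4-fold (0.000513), Fosb 3.8-fold (0.00373), Junb 2.76-fold (0.0034), the mRNA decay factor Zfp36 1.98-fold (0.00347) and Zap70, the kinase that relays the receptor signal, 1.8-fold (0.00504). Egr1 was 2.23-fold lower (adjusted p = 0.0139), a call lost without the stimulated array of WT mouse 3 (0.0506) or of ElkSapKO mouse 1 (0.0816) or 2 (0.0656). With a gene's probe sets averaged, Ncoa7 (0.142) and Zap70 (0.0902) were not called. Both states, measured in the same mice, shared 305 called genes, each in the same direction.

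In untreated ElkSapKO, receptor signalling components were lower in 7 of 26 genes, Cd5, Cd3g and Grb2 among them (18 adjusted over the list alone; camera adjusted p = 2.84e-08, adjusted p = 0.115 with an estimated correlation). Positive selection and maturation genes were lower in 7 of 28, Ccr7 and S1pr1 among them (12 lower and 1 higher over the list alone; 4.32e-06, adjusted p = 0.0573 with an estimated correlation). The family of ternary complex factors and Srf was lower in 4 of 18 genes (7 over the list alone, Elk1, Elk3 and Elk4 among them; 4.32e-06, and 0.00398 with an estimated correlation). Without the targeted genes Elk1 and Elk4 it was lower in 3 of 16 (5 over the list alone; 0.000315, and 0.0206 with an estimated correlation). ERK feedback regulators were lower in 3 of 20 (7 over the list alone; 0.00473, adjusted p = 0.134 with an estimated correlation). TCF-SRF genes (0 of 24; Junb lower over the list alone), NF-kB targets (0 of 21; 2 lower and 1 higher over the list alone) and DP genes (1 of 22 lower; 4 lower and 1 higher over the list alone) were called as lower. Their camera adjusted p were 0.0285, 0.0285 and 0.0303, with adjusted p = 0.378, 0.323 and 0.323 with an estimated correlation. Cd5 was 2.22-fold lower (adjusted p = 0.0242), but not without the untreated array of WT mouse 1 (0.176) or 3 (0.0505) or of ElkSapKO mouse 1 (0.0904). Cd3g (log2 −0.48, adjusted p = 0.0363) was not called without WT mouse 1 (0.0994), 2 (0.102) or 3 (0.112) or ElkSapKO mouse 2 (0.101), nor Grb2 (log2 −0.62) without WT mouse 1 (0.0741).

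In stimulated ElkSapKO, TCF-SRF genes were lower in 9 of 24, Egr2, Fosb, Junb and Zfp36 among them (12 over the list alone; camera adjusted p = 3.98e-07, adjusted p = 0.065 with an estimated correlation). The Egr, Nab and Id3 axis was lower in 5 of 12 (8 lower and 1 higher over the list alone; 5.17e-06, and 0.0236 with an estimated correlation). MRTF-SRF genes were lower in 4 of 22, Zyx among them (11 over the list alone; 1.19e-05, adjusted p = 0.109 with an estimated correlation). Receptor signalling components were lower in 9 of 26, Zap70 among them (17 over the list alone; 4.14e-07, adjusted p = 0.0828), and positive selection genes in 4 of 28 (12 lower and 1 higher over the list alone; 4.91e-05, adjusted p = 0.065). The family of ternary complex factors and Srf was lower in 5 of 18 (7 over the list alone; 0.000561, and 0.0276 with an estimated correlation). Without Elk1 and Elk4 it was lower in 4 of 16 (6 over the list alone; 0.0111, adjusted p = 0.0694 with an estimated correlation). Also called as lower were AP-1 genes (3 of 14; 5 over the list alone; 0.00019), Nr4a genes (3 of 15; 9 over the list alone; 0.00258) and ERK feedback regulators (6 of 20, with Dusp5, Dok1 and Dok2; 8 lower and 1 higher over the list alone; 0.00148). NFAT targets were too (4 of 18; 5 over the list alone; 0.0307), as were p53 and apoptosis genes (1 of 18, Bbc3; 2 over the list alone; 0.046). With an estimated correlation these 5 lists had adjusted p = 0.109, 0.111, 0.0828, 0.0908 and 0.0828. Zyx (log2 −1.35, adjusted p = 0.00601) was not called without the stimulated array of ElkSapKO mouse 1 (0.0524). With the spike-in level as a term neither Zyx (0.0592) nor Dusp5 (log2 −0.93, 0.00975 without the term) was called (0.0679 for Dusp5).

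Array quality differed between ElkSapKO and WT, and the counts of ElkSapKO differences moved both ways with single arrays and settings. The mean 3′ minus 5′ signal of Actb was 0.714 in ElkSapKO against 0.224 in WT, and all ElkSapKO arrays but only 2 of 6 WT arrays had a high spike-in. With the spike-in level as a term, 74 genes were called untreated and 170 stimulated; within the arrays of high spike-in, with 1 WT array per state, 3 and 5 were called. The log2 changes kept a median 0.931 and 0.903 of their size with the term and 0.896 and 0.988 within those arrays, with the same sign in all 626 and 1242 genes. These genes were picked on arrays that both fits use again, so the kept size and sign are no independent support. Array weights gave 5860 and 3955, and every probe set tested 1933 and 2082. Without the untreated array of ElkSapKO mouse 2, 2344 stimulated genes were called. Quantile normalization applied again gave 213 higher and 142 lower untreated, and 416 and 530 stimulated. The excess of lower genes was thus reversed in untreated cells and reduced in stimulated cells, so it depends on the scaling. With only the groups compared in the fit, 2 untreated genes, Ctse and Nmnat1, and 414 stimulated genes were called. With 1 array of that state left out, the untreated count was 64, 164 and 382 without WT mouse 1, 2 and 3, and 306 and 4927 without ElkSapKO mouse 1 and 3. The stimulated count was 551, 405 and 676 without WT mouse 1, 2 and 3, and 169, 371 and 2114 without ElkSapKO mouse 1, 2 and 3.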

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

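All tests of explanations in this part were chosen after the results were seen; the counts of other splits were planned.

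Differences in response between genotypes passed for 7 genes when adjusted over a gene list alone, and none of them passed over all 18193 genes. The rise of Egr2 differed by −2.003 in SapKO and −2.06 in ElkSapKO from WT, and by −1.73 in ElkSapKO from ElkKO (log2). In ElkSapKO against WT, Egr3 differed by −1.01 (adjusted p = 0.0129 over the list alone), Fosb by −1.86 (0.0128) and Klf1, an erythroid factor with a mean signal of 4.79 log2 over the arrays, by −0.95 (0.0203). Against SapKO, the response of ElkSapKO differed by −1.46 for the chemokine receptor Ccr4 (0.0451) and by 0.66 for Xist (0.0264), which is at a mean of 4.44 in these male mice. Against ElkKO it differed by −0.71 for the collagen gene Col1a2 (0.0341), at a mean of 4.63. Of 9160 probe sets with no listed symbol, 22 were called in the WT response, 20 of them higher and by at most 2.09.

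First, the rise of Egr2 was smaller in the mice lacking Sap than in those having it, with a log2 difference of −1.87 ± 0.322 (0.0934 adjusted over all genes, 0.561 with mouse as a block), a contrast picked because SapKO and ElkSapKO had shown it. Against the array that stands apart as the source, the difference was −2.04 without it (adjusted p = 0.00396, range over the alternatives with that mouse out or arrays weighted 0.00133 to 0.0137). A labelling batch, inferred only from the spike-in levels, is argued against by the difference within each level, −1.73 ± 0.581 among the mice with low spike-in (2 lacking Sap, 2 having it) and −1.94 ± 0.411 among those with high (4 and 4). A weaker stimulation of all induced genes is argued against by the median ratio to mice having Sap over the 45 other induced genes. It was 0.986 to 1.15 in the mice lacking Sap, while the ratio of Egr2, whose untreated signal was near background, was 0.737. With signals below 5.07 raised to it, these were 0.961 to 1.15 and 0.734. Over the 14 other genes induced at least 4-fold the median ratio was 0.824 to 0.972, and 11 of the 14 had a ratio below 1. Fosb, also near background in untreated cells, was lowest at 0.725 (0.393 with signals raised), below Egr2. Junb was at 0.801, Ier2 at 0.804 and Zfp36 at 0.806. A weaker rise shared by such immediate early genes thus stays open, as do loss of Sap and strain DNA carried with the knockout, neither of which was tested as a cause.

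The genes called in untreated SapKO that lie near each other were weighed next. Of the 14 called genes besides Elk4, 8 had another of these within 10 tested genes, against a mean of 0.202 and at most 4 in 1000 random sets (permutation p = 0.001, the smallest these can give), which DNA of another strain in several segments could give. The pair of Gcsh and Cmc2 was not particular to mice lacking Sap. Over both states, Gcsh averaged 8.99 log2 in ElkKO, 9.13 in SapKO and 6.86 in WT, and Cmc2 9.48, 9.93 and 8.57. DNA around Elk4 alone is argued against, since 3 of the 14 other called genes were on chromosome 1 and the rest elsewhere. For 6 of these genes (Cmc2, Gcsh, Nnt, Rbp7, Slc41a1 and Usp18), an ElkSapKO mouse had both arrays nearer to the WT mean than to the SapKO mean. This cannot decide on loss of Sap alone, because the genes were picked as far from WT in SapKO. ElkSapKO mice also lack Elk, and their arrays differ in quality. Strain segments and loss of Sap stay open as candidate explanations, not as findings, because no genotype was measured here.

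The many genes that differ between ElkSapKO and WT were weighed last. A labelling batch, which the labels do not give, is implied only by the 2 spike-in levels. With that level as a term, the 1242 genes called in stimulated cells kept a median 0.903 of their log2 change (interquartile range 0.834 to 0.979). All 1242, which were picked on the same arrays, kept their sign. In that fit 170 calls were left as the median standard error rose from 0.178 to 0.196. The level varied only within WT and SapKO, so this argues only against the step between the 2 levels. A labelling difference shared by ElkKO and ElkSapKO alone cannot be told apart from genotype, as dap was at 9.94 to 10.3 in ElkSapKO and at most 9.55 in WT. Without the array that stands apart, 703 genes were called in untreated cells, compared with 626. Counts also rose in contrasts that do not hold this array, which enters them through the pooled variance. The count thus cannot decide whether the array was a source of the untreated differences. The stimulated comparison does not hold it. RNA quality cannot be told apart from genotype: the 3′ minus 5′ signal of Actb was higher by 0.49 in ElkSapKO, with 0.545 to 1.05 there and 0.151 to 0.359 in WT. Loss of both factors stays open as well. The differences may come from it, from RNA quality or from a labelling difference shared by the arrays lacking Elk. In untreated cells the array that stands apart may add to them.

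Other splits of the same arrays were counted for each contrast. For the responses, the 10 splits are too few for a share under 0.05: as many genes came from 1 split in WT (64 genes, highest of the other splits 0), 1 in SapKO (66, 0), 1 in ElkKO (37, 1) and 3 in ElkSapKO (63, 1966). The split with 1966 keeps the arrays of mice 1 and 3 together and parts those of mouse 2, whose untreated array stands apart, which points to a structure of the ElkSapKO samples, and splits that part as many pairs as the real one gave at most 0 in each genotype. For the genotype comparisons 1 of 10 splits, the real one, gave as many, again too few: untreated 15, 18 and 626 genes (others at most 0, 0 and 1) and stimulated 13, 40 and 1242 (others at most 0, 0 and 0) in SapKO, ElkKO and ElkSapKO. For the averaged response 2 of 100 splits, the real one among them, gave as many as 264, a share under 0.05. The other of these gave 297, so chance is made unlikely but is not excluded. For the response differences, counted at an unadjusted p under 0.05, the splits were again too few for a share under 0.05. In each, splits other than the real one also gave as many, so chance cannot be excluded. The splits were 8 of 10 for SapKO (143, highest other 282), 4 for ElkKO (165, 409), 4 for ElkSapKO (982, 3007), 5 for ElkSapKO against SapKO (361, 1208) and 4 against ElkKO (625, 2002). For non-additivity 54 of 100 splits gave as many as 185, the highest 1492, so chance cannot be excluded. The high other counts in the differences also point to a structure of the samples.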

How the results depend on the processing

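The alternatives that leave out the array that stands apart or its mouse, weight the arrays, add the spike-in level (read as a labelling batch) or exchange ElkKO numbers, the mouse-wise fits of added contrasts, and the contrasts over genotypes lacking Sap or Elk, were chosen after seeing the data; the rest were planned. With mouse as a block, none of the 17 counts moved by over 1.5 times. Leaving out each array of the groups compared kept 2516 of 2892 values of named genes on their side of the threshold, and the batch term 259 of 332. Among the genes named by the rule, Gigyf2 reversed in untreated ElkKO, at 0.0171 with a gene's probe sets averaged, since its probe sets moved oppositely. Elk4 reversed on 1 of its dimmer probe sets. Signal over background limits folds: for 18 of 211 named values the lower group was within the range of Xist. For the others below, unless the setting itself leaves out genes or arrays, the cause was not tested.

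Counts without the array that stands apart were WT response 100, SapKO response 100, averaged 493, untreated ElkKO 106, stimulated SapKO 27, ElkKO 264 and ElkSapKO 2344, SapKO response difference 1, lacking Sap response 2 and both states 356. With both arrays of that mouse out they were WT response 98, ElkSapKO response 41, averaged 450, untreated ElkKO 96, stimulated SapKO 30 and ElkKO 231, response differences of SapKO 1 and ElkSapKO 1, lacking Sap response 2 and both states 277. With array weights the responses were WT 142, SapKO 229, ElkKO 186, ElkSapKO 696 and averaged 1091. Weighted, SapKO, ElkKO and ElkSapKO gave 42, 964 and 5860 untreated and 47, 931 and 3955 stimulated. Weighted response differences were 1 (SapKO), 3 (ElkSapKO against SapKO), 8 (against ElkKO) and 1 (non-additivity), and lacking Sap 2 (response), 2468 (untreated) and 3520 (both states). With the batch term, untreated ElkKO and ElkSapKO gave 5 and 74, stimulated 11 and 170. The exchanged ElkKO block gave 407 for the averaged response. For lacking Sap over both states, mouse as a block gave 77, and both arrays of a mouse averaged 28, where 137 were called with arrays as separate.

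With only the groups compared in the fit, counts were SapKO response 157, ElkSapKO response 15, untreated SapKO 35 and ElkSapKO 2, stimulated ElkSapKO 414 and SapKO response difference 2. At least 2-fold changes gave averaged 48, untreated ElkKO 7 and ElkSapKO 93, and stimulated 14 and 197. With every probe set tested, untreated ElkKO gave 39 and ElkSapKO 1933, stimulated ElkSapKO 2082, and the response differences of SapKO, ElkSapKO and ElkSapKO against ElkKO 1, 1 and 1, each Egr3. With probe sets averaged, untreated and stimulated ElkKO gave 9 and 21, and the same differences 1, 1 and 1, again Egr3. Median centring gave 8 for untreated ElkKO. Quantile normalization again gave 355 for untreated ElkSapKO and 1 for the SapKO response difference, Ncoa7. Without genes below 6, untreated ElkSapKO gave 955, stimulated SapKO 20 and ElkKO 67.

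With the TCF-SRF list in place of the induced genes, the response score differed from WT by −0.321 in SapKO and −0.263 in ElkSapKO. With ElkKO numbers exchanged, the score of ElkKO differed by −0.213. The 3 dimmer Elk4 probe sets differed from WT by −0.844, 0.0237 and −1.21 in untreated SapKO and by −0.548, 0.54 and −0.707 in ElkSapKO.

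Lists called without genes below 6 changed from 1 to 2 in untreated ElkKO, 7 to 2 in untreated ElkSapKO, 3 to 1 in stimulated ElkKO, and in response differences 3 to 5 (SapKO), 2 to 6 (ElkKO), 5 to 3 (ElkSapKO) and 0 to 1 (ElkSapKO against ElkKO). With an estimated correlation the lists called went in responses from 10 to 6 (WT), 11 to 7 (SapKO), 8 to 5 (ElkKO), 9 to 5 (ElkSapKO) and 12 to 7 (averaged). In SapKO, ElkKO and ElkSapKO they went from 3 to 1, 1 to 0 and 7 to 1 untreated and 6 to 2, 3 to 0 and 11 to 2 stimulated, and in the differences from 3, 2, 5 and 2 (ElkSapKO against SapKO) to 0.

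The next ranges leave out in turn each array of the groups in a contrast. Arrays of other groups, which enter through the pooled variance, are not in them. Counts were 35 to 62 in the WT response (lowest without stimulated WT mouse 2), 47 to 52 in SapKO, 21 to 39 in ElkKO (lowest without untreated mouse 3) and 36 to 216 in ElkSapKO (without stimulated mouse 2, and untreated mouse 3). They were 216 to 493 in the averaged response. Untreated, with 1 of the 6 arrays compared left out, they were 8 to 11 in SapKO, 3 to 22 in ElkKO and 64 to 4927 in ElkSapKO. Stimulated, they were 8 to 11, 3 to 26 and 169 to 2114. In the response difference of ElkSapKO against ElkKO they were 0 to 1 (Clcn1, without untreated ElkSapKO mouse 3), and 0 in the other differences without an array of their own groups. That of SapKO against WT had Ncoa7 called without the untreated array of ElkSapKO mouse 2, which is of another group.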

Other observations

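The test of paired numbers in this part was chosen after the correlations were seen, and the genes and levels given here were chosen after their values were seen, apart from the sex-linked genes.

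Some genes varied between mice within a genotype. Slc15a2, a peptide transporter, ranged from 3.08 to 11.02 log2 over the 24 arrays. Xist was at 4.07 to 5.07 and the Y-linked genes Eif2s3y at 8.33 to 9.71, Kdm5d at 5.59 to 8.26 and Uty at 5.32 to 7.24 in all arrays, whose labels give male mice. With both arrays of each mouse averaged, so that limma tests 12 mice, Ncoa7 was lower over both states in the mice lacking Sap (log2 −1.84 ± 0.0843, adjusted p = 3.64e-08), as was Nab2 (−0.92 ± 0.153, adjusted p = 0.0319). In that contrast 10 genes were higher and 18 lower. In untreated cells alone 9 were higher and 14 lower.

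In exact permutation tests over the 12 mice, with 924 splits, the response was smaller in mice lacking Sap for the second probe set of Egr2 (−1.52, p = 0.0022, the smallest possible), and the brightest of Egr3 (−0.70, p = 0.0043). The same tests gave a smaller response for the second of Egr3 (−2.55, exact p = 0.0022) and the brightest of Ncoa7 (−1.06, p = 0.0043), but not for the second of Ncoa7 (0.448, exact p = 0.4). Since these genes were picked on the same mice, the p values are no independent evidence. Egr1 differed by −0.54 (exact p = 0.065), and Nab2, Fos, Nr4a1 and Cd69 had exact p of 0.21, 0.68, 0.66 and 0.88. For lack of Elk, Egr2 had an exact p of 0.78, Fosb differed by −1.20 (exact p = 0.056) and Nab2 by −0.64 (exact p = 0.015). With ElkKO numbers 1 and 2 exchanged, the exact p was 0.0022 for the brightest of Egr3, 0.056 for Egr1, 0.77 for Egr2 by Elk, 0.019 for Fosb by Elk and 0.015 for Nab2 by Elk, while that of both Egr2 probe sets and the second of Egr3 by Sap stayed at 0.0022 and that of the brightest of Ncoa7 at 0.0043.

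The ElkKO arrays paired across mouse numbers. Over 50 genes chosen in the other 3 genotypes as differing between mice, untreated mouse 1 correlated at 0.97 with stimulated mouse 2, and untreated mouse 2 at 0.96 with stimulated mouse 1. With their own numbers they correlated at −0.67 and −0.63, and mouse 3 with its own number at 0.95; these correlations are across genes, which are not independent replicates. A candidate explanation is that numbers 1 and 2 were exchanged in 1 treatment, which could be tested with genotyping of the RNA.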
